A study of Pseudomonas aeruginosa with 9 samples.

How the data were processed

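The data are 9 arrays of the Affymetrix GeneChip for Pseudomonas aeruginosa, 3 for untreated cultures at 0 min and 3 each for cultures exposed to 0.008 mM chlorhexidine diacetate for 10 and 60 min. Per the labels, overnight cultures of 17 h were diluted into LB broth and shaken at 250 rpm and 37 °C until the OD600 reached 0.8. For the treated cultures the labels add a further dilution in fresh, warmed broth, which they do not mention for the untreated ones. RNA was isolated with a column kit, and 12 µg were used to make biotinylated cDNA. The deposited values are an intensity for each probe set and array, on a linear scale with 1 decimal and without values below 0. The submitters' processing notes name the program GCOS without a version, and its settings are not given in the sources used here. The strain is not stated in the labels.

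The design, the gene lists, the named-gene rule and most alternatives were fixed before the data were examined. The rule for scaling was one of these choices: signals were to be used as deposited if the 2%-trimmed means of the arrays lay within 10% of their median, and quantile normalized otherwise. The trimmed means ran from 32.2 to 101, a ratio of 3.14, so the log2 signals were quantile normalized. Signals of 0 were set to the smallest positive value of their array. The 14 control probe sets were left out, and so was the 20% of the other 5882 with the lowest mean log2 signal, which left 4705. Of these, 4562 were for genes, 126 for intergenic regions and 17 for rRNA and tRNA. Gene names came from the probe table of the platform and the RefSeq gene table of strain PAO1. As the probe table names no genome build, positions are not given.

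The arrays were fitted in 1 linear model with 3 groups in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit, eBayes with a variance trend). Contrasts were 10 min against 0 min, 60 min against 0 min and 60 min against 10 min, and p-values were two-sided and adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. Errors of log2 changes are the SE of that fit with 3 arrays per group. The number of arrays limits the precision. Shifts of 25 gene lists were tested with camera (inter-gene correlation 0.01), adjusted over the 75 list tests, and again with camera with an estimated correlation and with fry, which tests whether the genes of a list move, on balance, in one direction. Of the 75 tests, 35 passed with the preset correlation, 5 with an estimated one and 41 with fry. Those that passed with an estimated correlation were efflux pumps at 10 min, the PhoPQ and PmrAB list at 10 min and from 10 to 60 min, and the flagellum list at 60 min and from 10 to 60 min. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

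Named genes were chosen by a rule. For both comparisons with untreated arrays it took the 10 largest increases and the 10 largest decreases among genes with a symbol that passed the test and had no overlap between groups, and the 3 largest of each among those without a symbol. From 60 against 10 min it took the 5 largest of each with a symbol. From each gene list it took up to 2 members with the largest increase and up to 2 with the largest decrease past the test, and 16 genes were always taken: mexC, mexD, oprJ, mexA, mexX, oprH, phoP, phoQ, arnB, pmrA, algU, recA, lexA, oprD, rpsA and groEL. The gene listed as mexX is named PA2019 here.

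The method was tested on simulated data of the same size. Of genes with a true log2 change of 0.5, 63.6% were recovered at 10 min and 60.6% at 60 min, and of those with a change of 1, 98.5% and 100%. False calls made up 5.95%, 7.98% and 6.13% of calls in the 3 contrasts. The simulated noise was normal and independent between genes, as many genes rose as fell, and arrays differed in brightness but not in spread. On the real arrays the SD of log2 gene signals averaged 1.02 untreated, 0.859 at 10 min and 0.735 at 60 min. These rates therefore do not cover errors that come from the spread of the arrays or from genes that change together.

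Alternatives were deposited signals without scaling, median centring, no filter or a filter on the lowest 40%, a pseudocount of 16, a floor at the 20th percentile, no variance trend, a fit to the 6 arrays compared only, a replicate block, a variance not pooled across genes, a threshold of 2-fold, the ratio of average signals, and each array left out in turn. Added after the data were seen were scaling to 3 bright Bacillus subtilis control probe sets, deposited signals for the ratio of average signals, genes above the 95th percentile of the intergenic probe sets, and a fit without the dimmest array of every group. For the gene lists, median centring, the filter on the lowest 40%, the pseudocount, the floor and the fit without a variance trend were also added then. The dimmest array of every group was its replicate 1. Replicate numbers were not used to pair arrays in the main fit. Detection calls were not used here. The 117 probe sets for genes of other strains fell below the filter.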

Results

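Transcript levels were measured in cultures of Pseudomonas aeruginosa, an opportunistic Gram-negative pathogen, before and after exposure to chlorhexidine diacetate, a cationic biguanide disinfectant that acts on bacterial membranes. Each of 9 Affymetrix arrays was hybridised with labelled cDNA. There were 3 arrays for untreated cultures at 0 min, 3 for cultures 10 min after addition of 0.008 mM chlorhexidine diacetate and 3 for cultures after 60 min. The labels do not say whether arrays with the same replicate number share a culture or day. The design text describes 3 independent experiments, and the comparisons ask how transcript levels differ between treated and untreated cultures. No untreated culture at 10 or 60 min was analysed here, and the labels describe a further dilution in fresh broth for the treated cultures alone. Exposure, time after the cultures reached an OD600 of 0.8 and this dilution therefore cannot be told apart in any value below.

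The arrays differed in overall brightness and in the spread of their signals. The 2%-trimmed mean deposited signal ran from 32.2 to 101. The ratio of the 95th percentile to the median of the gene probe sets was 2.82 ± 0.0793 (SD, n = 3) on untreated arrays, 2.43 ± 0.0764 (n = 3) at 10 min and 2.13 ± 0.0356 (n = 3) at 60 min. Intergenic probe sets lay close to the gene probe sets, with a median of 0.709 ± 0.0367 (SD, n = 3) of the gene median on untreated arrays and 0.823 ± 0.0467 (n = 3) at 60 min. Quantile normalization gives all arrays 1 common spread, while median centring keeps the narrower spread of the treated arrays. Fold changes of bright genes therefore depend on this choice, most of all at 60 min. Median centring was planned for single genes, and its use on gene lists was added after the data were seen. Deposited signals, median centring and control scaling differ only by a constant for each array. Sizes relative to all tested genes are therefore the same under them by construction, and only the calls can differ. Arrays of one group correlated at r = 0.900 to 0.952 across probe sets, and arrays of different groups at r = 0.778 to 0.904.

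**Figure D1:**
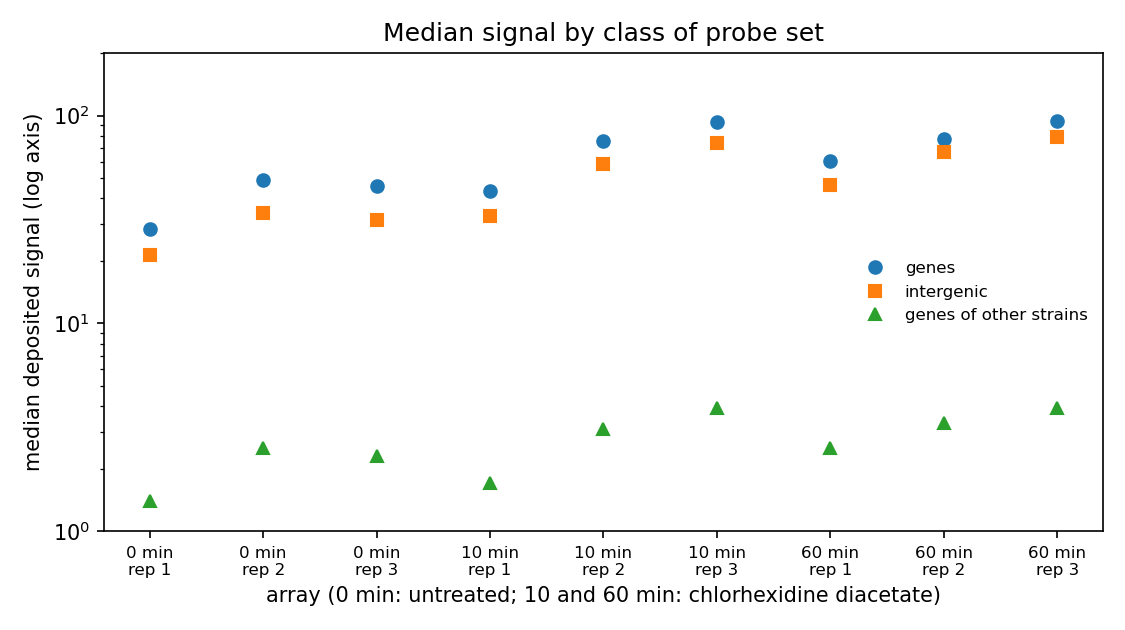
Median deposited signal (log axis) of the gene, intergenic and other-strain probe sets on each of the 9 arrays, 1 point per class and array. Intergenic medians lie at 0.683 to 0.860 of the gene medians and at 13.6 to 20.2 times the medians for genes of other strains.

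After 10 min of exposure, the genes of the MexCD-OprJ efflux pump, a multidrug exporter of the resistance-nodulation-division family, rose together. The membrane fusion gene mexC (PA4599) rose 13.1-fold, from a normalized signal of 34.1 ± 3.89 to 444 ± 32.1 (SD, n = 3 arrays each), with a log2 change of 3.71 ± 0.22 (SE; limma, adjusted p = 7.21e-07). Its untreated signal was dim, and intergenic signal near gene signal limits how far the size of this fold can be read. The pump gene mexD (PA4598) rose by 2.49 ± 0.20 (adjusted p = 8.39e-06), the outer membrane channel gene oprJ (PA4597) by 1.26 ± 0.17 (adjusted p = 0.000614) and nfxB (PA4600), which encodes the repressor of the operon, by 1.85 ± 0.16 (adjusted p = 1.38e-05). The gene of the main constitutive pump, mexA (PA0425), did not pass the test (log2 change 0.17 ± 0.14, adjusted p = 0.496; -0.04 after median centring). Of 32 tested members of the efflux list, 6 rose and none fell among all genes tested, and 9 rose with p adjusted over the list alone. The list shifted up by a mean of 0.41 (camera, adjusted p = 0.000146; adjusted p = 0.0480 with an estimated correlation). Its median was 0.17, and the members that rose were the neighbours mexC, mexD, nfxB and oprJ, besides PA4990 and PA2019. The mean thus rests largely on 1 locus.

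Genes of the PhoPQ and PmrAB systems, which respond to cationic compounds and direct the modification of lipid A, also rose at 10 min. The outer membrane protein gene oprH (PA1178) rose by 2.04 ± 0.22 on the log2 scale (adjusted p = 9.28e-05). PA4773, which lies just upstream of the pmrAB genes, rose by 1.78 ± 0.12 (adjusted p = 2.64e-06) and arnB (PA3552), needed for the addition of aminoarabinose to lipid A, by 1.15 ± 0.14 (adjusted p = 0.000272). The response regulator gene pmrA rose by 0.80 ± 0.12 (adjusted p = 0.00125), whereas phoP (0.29 ± 0.16, adjusted p = 0.310) and phoQ (0.19 ± 0.14, adjusted p = 0.470) did not pass. Of 17 tested members 10 rose (9 also after median centring) and none fell, and 11 rose with p adjusted over the list alone. The list's mean shift was 0.68 (adjusted p = 1.63e-10; adjusted p = 0.0250 with an estimated correlation).

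**Figure D2:**
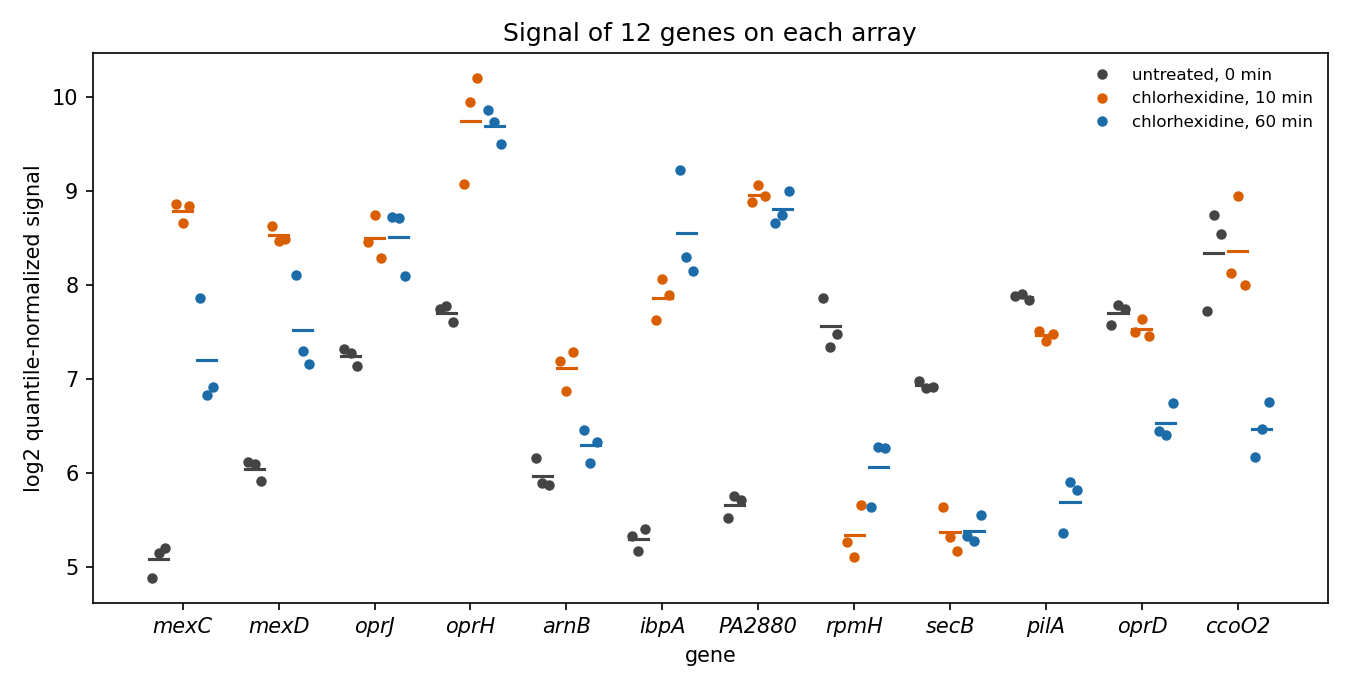
Quantile-normalized log2 signal of 12 genes on each of the 9 arrays, with 1 point per array, coloured by group, and a bar at the mean of each group of 3. The mexC points lie higher at 10 min (log2 change 3.71) and at 60 min (2.12) than on untreated arrays, and those of pilA are lowest at 60 min (-2.18), while the oprJ change at 60 min falls from 1.27 to 0.23 after median centring.

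Chaperone genes rose at 10 min as well. The small heat shock protein gene ibpA (PA3126) rose 5.91-fold (log2 2.56 ± 0.22, adjusted p = 1.38e-05), the disaggregase gene clpB by 1.18 ± 0.22 (adjusted p = 0.00424) and the chaperone gene dnaK by 0.99 ± 0.14 (adjusted p = 0.000907). The untreated ibpA signal was dim as well, so the same limit holds for its fold as for that of mexC. The chaperonin gene groEL did not pass (0.37 ± 0.13, adjusted p = 0.111; -0.34 after median centring). In the heat shock list 7 of 16 members rose and none fell (10 rose with p adjusted over the list alone), with a mean of 0.57 (adjusted p = 8.70e-07; adjusted p = 0.0788 with an estimated correlation; mean 0.34 after median centring). In the envelope stress list 3 of 18 rose, 8 with p adjusted over the list alone (mean 0.31, adjusted p = 0.000374; adjusted p = 0.0604 with an estimated correlation). The phosphate starvation list had 4 of 11 members higher, the same number over the list alone, among them pstS (1.02 ± 0.16) and the regulator gene phoB (0.98 ± 0.16), with a list mean of 0.28 (adjusted p = 0.0235; adjusted p = 0.131 with an estimated correlation). The R- and F-type pyocins, phage-tail-like bacteriocins, shifted up by 0.22 with 2 of 30 members past the test and 6 over the list alone (adjusted p = 0.000109; adjusted p = 0.170 with an estimated correlation). Outside the lists, PA2880 rose 9.86-fold (log2 3.30 ± 0.12, adjusted p = 3.76e-09), PA5212 by 1.93 ± 0.17 and PA1343 by 1.79 ± 0.12 on the log2 scale. The tryptophan synthase gene trpB rose by 1.86 ± 0.15 and rsmA, which encodes an RNA-binding post-transcriptional regulator, by 1.68 ± 0.19.

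Parts of the ribosomal protein, NADH dehydrogenase and fatty acid synthesis lists fell at 10 min. The largest falls with a gene symbol were those of the ribosomal protein genes rpmH (log2 -2.22 ± 0.19, adjusted p = 1.38e-05) and rpsT (-2.13 ± 0.17, adjusted p = 1.05e-05). Next came the export chaperone gene secB (-1.56 ± 0.13), the elongation factor P gene efp (-1.53 ± 0.16) and the 16S rRNA processing gene rimM (-1.51 ± 0.16). Of 53 tested ribosomal protein genes 15 fell and none rose (25 fell with p adjusted over the list alone), with a mean of -0.50 (adjusted p = 7.85e-13; adjusted p = 0.258 with an estimated correlation; mean -1.11 after median centring). The ribosomal call was lost with fry (adjusted p = 0.0509). Among 13 fatty acid synthesis genes 8 fell, and of those over the list alone 8 fell and 1 rose. Examples were fabA (-1.06 ± 0.13, adjusted p = 0.000331) and fabF1 (-0.88 ± 0.13, adjusted p = 0.00125), and the list mean was -0.50 (adjusted p = 2.95e-07; adjusted p = 0.0655 with an estimated correlation). In the NADH dehydrogenase list, the first enzyme of the respiratory chain, 5 of 12 genes fell (6 over the list alone), led by nuoB (-1.20 ± 0.20) and nuoD (-1.19 ± 0.15). The list mean was -0.47 (adjusted p = 2.61e-05; adjusted p = 0.0965 with an estimated correlation). The TCA cycle list had 5 lower members, including icd (-0.90 ± 0.18), and 1 higher, acnA (0.80 ± 0.16), and over the list alone 7 lower and 1 higher (mean -0.30, adjusted p = 6.36e-05; adjusted p = 0.189 with an estimated correlation; mean -0.58 after median centring). The flagellum list had 3 of 34 members lower, 7 over the list alone, and a mean of -0.13 (adjusted p = 0.00881; adjusted p = 0.0788 with an estimated correlation). With deposited signals (adjusted p = 0.111) and with Bacillus subtilis control scaling (adjusted p = 0.105), a scaling chosen after the data were seen, the list did not pass, while its size relative to all tested genes stayed at -0.13. Among genes brighter than the 95th percentile of the intergenic probe sets only 2 members were tested, with a mean of 0.15 relative to all tested genes and no call (adjusted p = 0.910). ATP synthase had 1 of 9 lower, 1 over the list alone (mean -0.24, adjusted p = 0.0339; adjusted p = 0.271 with an estimated correlation; mean -0.77 after median centring). The ATP synthase call was lost with fry (adjusted p = 0.0722) and without untreated replicate 1 (adjusted p = 0.113), 10 min replicate 2 (adjusted p = 0.136) or 10 min replicate 3 (adjusted p = 0.0982).

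The other 13 lists did not shift past the test at 10 min. Single members changed in some of them: the nitrate reductase gene narG rose by 1.20 ± 0.19 in the denitrification list (4 of 27 higher, 1 lower, and 6 and 1 over the list alone; adjusted p = 0.284). After median centring 1 of these 4 passed, and the list mean turned from 0.08 to -0.07. The helicase gene recQ fell (-1.07 ± 0.19) in the DNA repair list (3 of 23 lower, and 3 lower and 1 higher over the list alone; adjusted p = 0.276). The superoxide dismutase gene sodB fell (-0.68 ± 0.13; -1.20 after median centring) in the oxidative stress list (1 of 12 lower, 1 over the list alone; adjusted p = 0.697). The type III effector gene exoS rose by 0.66 ± 0.13 (1 of 28 higher, 1 over the list alone; adjusted p = 0.354). Type IV pili had 2 of 24 lower, 2 over the list alone (adjusted p = 0.104), including pilG (-1.01 ± 0.16), and iron acquisition 1 of 21 higher, 1 over the list alone (adjusted p = 0.127). Porins had 1 of 26 lower and none over the list alone (adjusted p = 0.127). The pili and porin lists passed as lower after median centring (adjusted p = 0.0227 and 0.0283), and the porin list also with deposited signals (adjusted p = 0.0401) and control scaling (adjusted p = 0.0407). No member passed in the lists of terminal oxidases (18 tested, adjusted p = 0.173), sulfate starvation (14, adjusted p = 0.788), quorum sensing (28, adjusted p = 0.930) and exopolysaccharides (26, adjusted p = 0.887), and none did over those lists alone. The terminal oxidase list passed as lower with deposited signals (adjusted p = 0.0111) and control scaling (adjusted p = 0.00952). The peptidoglycan list (2 of 20 lower, 3 over the list alone; adjusted p = 0.794) and the amino acid uptake list (1 of 15 higher, and 1 higher and 1 lower over the list alone; adjusted p = 0.774) each had a test that pointed down. Their medians were 0.03 and 0.000457 and their means -0.00187 and -0.02.

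In all, 351 of 4705 tested probe sets changed at 10 min (143 higher, 208 lower; limma, Benjamini-Hochberg adjusted), of which 57 changed at least 2-fold (29 higher, 28 lower), and 1047 had an unadjusted p under 0.05. By the ratio of average signals, the measure the design text names, 29 were at least 2-fold higher and 27 lower. The groups did not overlap for 30.5% of probe sets, where chance gives 10%. Median centring gave 660 changed probe sets (176 higher, 484 lower), 333 of them among the 351 and in the same direction. The count was 207 without untreated replicate 2, 209 without untreated replicate 3, 201 without 10 min replicate 2 and 225 without 10 min replicate 3.

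After 60 min, the pump and chaperone genes ibpA, mexC and mexD were still above the untreated level. Members of the lists for ribosomal proteins, the TCA cycle, the respiratory chain, the flagellum and pili had fallen, as had single porin genes. Of these lists only the flagellum list passed with an estimated correlation. The chaperone gene ibpA was 9.56-fold higher (log2 3.26 ± 0.22, adjusted p = 3.68e-06) and PA2880 8.83-fold (log2 3.14 ± 0.12, adjusted p = 6.99e-09). The pump gene mexC was 4.35-fold higher (log2 2.12 ± 0.22, adjusted p = 6.77e-05) and mexD 2.79-fold (log2 1.48 ± 0.20, adjusted p = 0.000349), with 3 arrays per group. The type IV pilus subunit gene pilA (PA4525) was 4.53-fold lower (log2 -2.18 ± 0.13, adjusted p = 1.37e-06). The basic amino acid porin gene oprD fell by 2.25-fold (log2 -1.17 ± 0.12, adjusted p = 6.77e-05).

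Several increases of bright genes at 60 min depended on the scaling. The oprH level was higher by 1.99 ± 0.22 (adjusted p = 0.000107) and by 0.67 after median centring, still past the test. The envelope stress sigma factor gene algU (PA0762) was higher by 1.40 ± 0.18 (adjusted p = 0.000277) and by 0.70 after median centring. The rsmA level was higher by 1.19 ± 0.19, and by 0.74 after median centring, and both genes passed the test either way. For oprJ (1.27 ± 0.17, adjusted p = 0.000374) and pmrA (0.71 ± 0.12, adjusted p = 0.00162) the call ended after median centring, at 0.23 and 0.29. The peroxidase gene ahpC was higher by 1.18 ± 0.14 (adjusted p = 0.000242) but at -0.35 after median centring. In the same way groEL was higher by 0.49 ± 0.13 (adjusted p = 0.0225) but lower, at -1.33, after it (adjusted p = 3.95e-05). The groEL call was also lost without untreated replicate 1 or 3 or 60 min replicate 1 or 2 (adjusted p = 0.0744, 0.0656, 0.0769 and 0.0652). The efflux list had 5 of 32 members higher, 5 over the list alone, and a mean of 0.26 (adjusted p = 0.0205; adjusted p = 0.101 with an estimated correlation), a call lost without the filter on dim probe sets (adjusted p = 0.0798). The list median was 0.16, and the higher members were mexC, mexD, oprJ, PA2020 and mexR. The pyocin list had 9 of 30 higher, 9 over the list alone (mean 0.23, adjusted p = 0.00120; adjusted p = 0.189 with an estimated correlation; mean 0.13 after median centring). The iron acquisition list had 4 of 21 higher, 5 over the list alone (mean 0.24, adjusted p = 0.00460; adjusted p = 0.189 with an estimated correlation), including the heme receptor gene phuR (0.55 ± 0.12). The PhoPQ and PmrAB list no longer passed (3 of 17 higher and 1 lower, the same over the list alone, mean 0.18, adjusted p = 0.265), and its mean was -0.03 after median centring.

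Ribosomal protein genes gave the largest mean fall of the 25 lists at 60 min. Of these genes 39 of 53 fell and none rose, 42 over the list alone. Among these, rpmC changed by -2.15 ± 0.22 (adjusted p = 6.77e-05), rplO by -1.76 ± 0.29 (adjusted p = 0.00141) and rpsA by -1.02 ± 0.20 (adjusted p = 0.00435; -1.89 after median centring). The list mean was -0.73 (adjusted p = 1.01e-18; adjusted p = 0.189 with an estimated correlation) and -1.94 after median centring. In the TCA cycle list 13 of 21 fell and 1 rose, 17 and 1 over the list alone, with sucA at -1.08 ± 0.18 and the succinate dehydrogenase gene sdhA at -1.06 ± 0.13 (-1.63 after median centring). The list mean was -0.62 (adjusted p = 1.82e-09; adjusted p = 0.0989 with an estimated correlation; mean -1.05 after median centring). NADH dehydrogenase genes fell in 10 of 12 cases, 11 over the list alone (mean -0.70, adjusted p = 1.47e-08; adjusted p = 0.0604 with an estimated correlation). Of 18 terminal oxidase and bc1 genes 7 fell, among them ccoO2 (-1.88 ± 0.27, adjusted p = 0.000692) and ccoN2 (-1.70 ± 0.30, adjusted p = 0.00216) of a cbb3-type oxidase. Over the list alone 8 were lower and 1 higher, and the mean was -0.49 (adjusted p = 0.00182; adjusted p = 0.0788 with an estimated correlation; mean -0.73 after median centring). ATP synthase genes fell in 5 of 9 cases, 5 over the list alone, with atpH at -1.51 ± 0.24, or -2.30 after median centring (mean -0.45, adjusted p = 0.00626; adjusted p = 0.189 with an estimated correlation; mean -1.47 after median centring). Fatty acid synthesis genes fell in 9 of 13 cases, 9 over the list alone, with fabB at -1.14 ± 0.13 and fabA at -1.13 ± 0.13 (mean -0.61, adjusted p = 5.45e-07; adjusted p = 0.0656 with an estimated correlation; mean -0.95 after median centring).

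Genes of the flagellum were also lower at 60 min, and smaller shares of the pilus and denitrification lists. In the flagellum and chemotaxis list 16 of 34 fell and none rose, 19 lower and 1 higher over the list alone, including the chemotaxis regulator gene cheY (-1.07 ± 0.11, adjusted p = 6.77e-05) and the filament cap gene fliD (-0.97 ± 0.11, adjusted p = 0.000194). The list mean was -0.33 (adjusted p = 1.63e-06; adjusted p = 0.0250 with an estimated correlation). Type IV pilus genes had 7 of 24 lower and 1 higher, 9 and 1 over the list alone, with pilQ, the outer membrane secretin gene, at -1.27 ± 0.18 (mean -0.27, adjusted p = 0.00587; adjusted p = 0.0788 with an estimated correlation; mean -0.43 after median centring). The higher member, chpA, was at 0.69 but at -0.09 after median centring. In the denitrification and arginine fermentation list 7 of 27 fell and 20 did not pass, 9 fell over the list alone, with the arginine-ornithine antiporter gene arcD at -1.89 ± 0.33 and the arginine deiminase gene arcA at -0.998 ± 0.17 (-2.48 after median centring). The list median was -0.09 and the mean -0.28 (adjusted p = 0.0140; adjusted p = 0.303 with an estimated correlation; mean -0.55 after median centring), a call lost with fry (adjusted p = 0.0722) and without untreated replicate 2 (adjusted p = 0.0572). The hydrogen cyanide synthase genes hcnA (-1.35 ± 0.21) and hcnC (-1.38 ± 0.18), the bacterioferritin gene bfrB (-1.57 ± 0.12) and the division gene ftsZ (-1.04 ± 0.17) fell too. Porins went both ways, with 6 of 26 lower, such as oprG (-1.43 ± 0.22; -2.41 after median centring) and oprE (-1.24 ± 0.12), and 3 higher, the same over the list alone. Their list did not pass (adjusted p = 0.240), and its median (0.01) and mean (-0.16) differed in sign. It passed as lower with deposited signals (adjusted p = 0.00362) and control scaling (adjusted p = 0.00398), but not after median centring (adjusted p = 0.102, mean -0.41 over 24 members). The porin list also passed with fry (adjusted p = 0.0105), for which no direction was recorded.

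The remaining lists did not shift past the test at 60 min. The heat shock list had 3 of 16 higher and 3 lower, 3 and 4 over the list alone (adjusted p = 0.431). Its mean (0.06; -0.49 after median centring) had the opposite sign to its median (-0.15) and its test, and the list passed as lower after median centring (adjusted p = 0.000236), with deposited signals (adjusted p = 0.00324) and with control scaling (adjusted p = 0.00393). The largest increase was that of ibpA, while the protease genes clpX (-1.18 ± 0.15) and clpP (-0.80 ± 0.19) fell. Envelope stress had 4 of 18 higher and 1 lower, 7 and 2 over the list alone (adjusted p = 0.104). Oxidative stress had 2 of 12 higher and 2 lower, 3 and 2 over the list alone (adjusted p = 0.409), with the catalase gene katA at -0.95 ± 0.21. Quorum sensing had 1 of 28 higher and 6 lower, 1 and 8 over the list alone (adjusted p = 0.0808), and the peptidoglycan and division list 1 of 20 higher and 4 lower, the same over the list alone (adjusted p = 0.326). Phosphate starvation had 2 of 11 higher, and 2 higher and 1 lower over the list alone (adjusted p = 0.480). Type III secretion had 2 of 28 higher, 1 over the list alone (adjusted p = 0.273), and exopolysaccharides 2 of 26 higher and 1 lower, 1 higher over the list alone (adjusted p = 0.779), with pelD at 0.46 ± 0.10. No sulfate starvation gene passed (14 tested, none over the list alone, adjusted p = 0.600). DNA repair had 1 of 23 lower and none over the list alone (adjusted p = 0.748), with a median of 0.05 and a mean of -0.04. That member was recA (-0.46 ± 0.14, adjusted p = 0.0369). Its call was lost in 5 of the 9 leave-one-out fits, those without untreated replicate 1, 2 or 3 or 60 min replicate 2 or 3, at values of -0.51 to -0.37. The repressor gene lexA did not pass (0.34 ± 0.12, adjusted p = 0.0694; -0.05 after median centring). Amino acid uptake had 1 of 15 higher and 3 lower, the same over the list alone (adjusted p = 0.604), with a median of 0.00688 and a mean of -0.07.

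Fewer of the higher list members passed at 60 min when the arrays were median centred. It kept 3 of the 5 efflux genes and 2 of the 3 porin genes. It kept 3 of the 9 pyocin genes (2 turned), 2 of the 4 iron genes (1 turned), 1 of the 3 PhoPQ and PmrAB genes (1 turned), 1 of the 4 envelope stress genes (1 turned), 1 of the 3 heat shock genes (2 turned) and 1 of the 2 oxidative stress genes (1 turned). In the lists of phosphate starvation, type III secretion and exopolysaccharides 1 of 2 was kept each. The single higher members of the TCA cycle, peptidoglycan and amino acid uptake lists did not pass. The lower members past the test among all genes passed in both scalings.

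At 60 min 867 of 4705 probe sets changed (395 higher, 472 lower), 99 of them at least 2-fold (29 higher, 70 lower), and 1577 had an unadjusted p under 0.05. By the ratio of average signals 30 were at least 2-fold higher and 69 lower. The groups did not overlap for 37.0% of probe sets, where chance gives 10%. Median centring gave 1038 changed probe sets (267 higher, 771 lower). It shared 658 calls and directions with the 867, and 44 of the 395 higher calls had the other sign under it. The count was 543 without untreated replicate 2, 510 without untreated replicate 3 and 577 without 60 min replicate 1.

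Of the probe sets tested, 218 changed at both times, 68 higher at both, 148 lower at both and 2 in opposite directions. Independent lists of these sizes would share 12.0 higher and 20.9 lower calls. The log2 changes at the 2 times correlated across genes, which are not independent replicates, at r = 0.682, against 0.499 (range 0.469 to 0.530) in 100 simulations of unchanged groups against the shared untreated arrays. The covariance was 0.0770 against 0.0101 simulated, a difference of 0.0669. The simulated groups shared no higher call and at most 1 lower call. As no gene changed in them, almost no probe set was called at either time. These counts therefore do not show how many shared calls the untreated arrays create among called genes. With 3 untreated arrays the controls could not be split between the comparisons, so part of the excess of shared calls may come from them. The overlap in one direction, 216 with all arrays, was 115 without untreated replicate 2, 119 without untreated replicate 3, 130 without 10 min replicate 2 and 129 without 10 min replicate 3.

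The difference between the exposure times was tested directly. From 10 to 60 min the mexC level fell (log2 -1.59 ± 0.22, adjusted p = 0.000913). So did the levels of nfxB (2.84-fold, log2 -1.50 ± 0.16, adjusted p = 0.000152) and mexD (2.01-fold, log2 -1.01 ± 0.20, adjusted p = 0.00856). The oprJ level did not pass (0.01 ± 0.17, adjusted p = 0.978), but fell by the median-centred values (-0.86, adjusted p = 0.000733). The PhoPQ and PmrAB list fell, with 6 of 17 members lower and 10 over the list alone (mean -0.49, adjusted p = 8.57e-09; adjusted p = 0.0250 with an estimated correlation). Lower members included PA4773 (-1.52 ± 0.12), PA1559 (-1.46 ± 0.14) and arnB (-0.82 ± 0.14), whereas oprH did not pass (-0.05 ± 0.22) except after median centring (-1.05, adjusted p = 0.000960). Heat shock genes fell in 8 of 16 cases, 11 lower and 1 higher over the list alone, led by dnaK (-1.38 ± 0.14) and the protease ATPase gene clpX (-1.30 ± 0.15) (mean -0.51, adjusted p = 8.57e-09; adjusted p = 0.0640 with an estimated correlation; mean -0.83 after median centring).

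The genes that fell most from 10 to 60 min were ccoO2 (-1.90 ± 0.27, adjusted p = 0.00138), pilA (-1.77 ± 0.13, adjusted p = 1.37e-05), rpmC (-1.72 ± 0.22), mexC and the O-antigen synthesis gene wbpG (-1.58 ± 0.20). The arginine deiminase pathway genes arcA (-1.36 ± 0.17), arcB (-1.31 ± 0.19) and arcC (-1.40 ± 0.16) fell together (arcA -2.20 and arcB -2.20 after median centring), in a list with 5 of 27 lower, 5 over the list alone (mean -0.37, adjusted p = 4.66e-06; adjusted p = 0.127 with an estimated correlation). The TCA list had 6 of 21 lower, 10 lower and 1 higher over the list alone, with sdhC at -1.06 ± 0.16 (mean -0.33, adjusted p = 8.21e-06; adjusted p = 0.189 with an estimated correlation). Terminal oxidases had 4 of 18 lower, 5 over the list alone (mean -0.36, adjusted p = 0.00636; adjusted p = 0.101 with an estimated correlation). The flagellum list had 5 of 34 lower, 8 over the list alone, with the flagellin gene fliC at -1.18 ± 0.19 and the hook gene flgE at -0.80 ± 0.12 (mean -0.20, adjusted p = 0.000135; adjusted p = 0.0480 with an estimated correlation).

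Among the genes that rose from 10 to 60 min, the ribosomal protein gene rpsT had the largest change (2.19 ± 0.17, adjusted p = 1.37e-05; 1.37 after median centring). The other ribosomal protein genes past the test, 14 of 53, fell (16 lower and 4 higher over the list alone). The algU level rose by 1.16 ± 0.18 (adjusted p = 0.00177; 0.60 after median centring). The calls of ahpC (1.01 ± 0.14) and secE (0.88 ± 0.13) ended after it, at 0.04 and 0.09. The ribosomal protein list mean was -0.23 (adjusted p = 0.000595; adjusted p = 0.543 with an estimated correlation; mean -0.83 after median centring). The call was lost with fry (adjusted p = 0.353) and without the dimmest array of every group (adjusted p = 0.938), where the mean was 0.02 relative to all tested genes. Relative to all tested genes it was -0.23 with all arrays, -0.12 without 10 min replicate 1 and -0.09 without 60 min replicate 1, where the call was lost, and -0.36 without 10 min replicate 2 and -0.40 without 60 min replicate 3. NADH dehydrogenase had 3 of 12 lower, and 5 lower and 1 higher over the list alone (adjusted p = 0.00672; adjusted p = 0.189 with an estimated correlation). Type IV pili had 2 of 24 lower and 1 higher, the same over the list alone (adjusted p = 0.0347; adjusted p = 0.131 with an estimated correlation). Quorum sensing had 5 of 28 lower, 7 over the list alone (adjusted p = 0.0297; adjusted p = 0.189 with an estimated correlation), a call lost after median centring (adjusted p = 0.0755). Iron acquisition had 1 of 21 higher, 1 over the list alone (adjusted p = 0.0422; adjusted p = 0.272 with an estimated correlation). After median centring that member did not pass, while the list did (adjusted p = 0.0335, mean 0.09 against 0.13). The iron list did not pass with deposited signals (adjusted p = 0.0783) or control scaling (adjusted p = 0.0737), at a size relative to all tested genes of 0.14 under both and 0.14 in the main fit. It did not pass without the filter on dim probe sets either (adjusted p = 0.0554). Without 10 min replicate 1 these 4 calls were lost (adjusted p = 0.0548, 0.0562, 0.0562 and 0.240). Without 60 min replicate 2 the calls of the pili list (adjusted p = 0.0761) and the iron list (adjusted p = 0.0761) were lost. So were those of the quorum sensing list without 60 min replicate 1 (adjusted p = 0.0749) and the iron list without 60 min replicate 3 (adjusted p = 0.0518).

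No shift past the test was found from 10 to 60 min in the other 14 lists. Porins had 3 of 26 lower, and 5 lower and 1 higher over the list alone (adjusted p = 0.690). ATP synthase had 1 of 9 lower, 4 over the list alone (adjusted p = 0.116), and fatty acid synthesis 2 of 13 lower, 4 over the list alone (adjusted p = 0.173). The medians of these lists lay above 0 (0.11, 0.02 and 0.000114), but their means (-0.07, -0.22 and -0.10) and tests pointed down. ATP synthase passed as lower with deposited signals (adjusted p = 1.08e-10) and control scaling (adjusted p = 4.36e-10). After median centring ATP synthase (mean -0.70, adjusted p = 7.38e-06), fatty acid synthesis (adjusted p = 0.0227) and envelope stress (adjusted p = 0.0335) passed as lower. The porin genes oprE (-1.12 ± 0.12) and oprD (-0.998 ± 0.12) fell. The efflux list had 4 of 32 lower, 4 over the list alone (adjusted p = 0.126), and passed as lower with deposited signals (adjusted p = 0.00941) and control scaling (adjusted p = 0.00684). It also passed with fry (adjusted p = 0.0129), for which no direction was recorded. Envelope stress had 1 of 18 higher and 3 lower, 2 and 5 over the list alone (adjusted p = 0.182). Oxidative stress had 2 of 12 higher (1 of them after median centring), and 2 higher and 1 lower over the list alone (adjusted p = 0.600). Phosphate starvation had 2 of 11 lower, and 4 lower and 1 higher over the list alone (adjusted p = 0.104). The peptidoglycan and division list had 2 of 20 lower, ftsZ (-0.89 ± 0.17) among them, 2 over the list alone (adjusted p = 0.276), and amino acid uptake 1 of 15 higher, none after median centring and 1 over the list alone (adjusted p = 0.521). No member passed, over all genes or over the list alone, in the lists of pyocins (30 tested, adjusted p = 0.937), DNA repair (23, adjusted p = 0.409), sulfate starvation (14, adjusted p = 0.738), type III secretion (28, adjusted p = 0.658) and exopolysaccharides (26, adjusted p = 0.593).

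The list calls also depended on the genes, arrays and test used. Among the 873 genes brighter than the 95th percentile of the intergenic probe sets 19 of the 35 calls were lost (adjusted p = 0.0532 to 0.910). At 10 min these were envelope stress, NADH dehydrogenase (-0.23 relative to all tested genes), ATP synthase, pyocins and flagellum. At 60 min they were efflux, NADH dehydrogenase, ATP synthase, denitrification, pyocins, iron, flagellum, pili and fatty acid synthesis, and from 10 to 60 min NADH dehydrogenase, iron, flagellum, pili and quorum sensing. Calls were gained there for porins at 60 min (-0.83 relative to all tested genes, adjusted p = 0.00564) and, from 10 to 60 min, for porins (-0.57, adjusted p = 0.00713) and efflux (-0.60, adjusted p = 0.0178). Without the dimmest array of every group the calls from 10 to 60 min were lost for NADH dehydrogenase (-0.13, adjusted p = 0.147), pili (adjusted p = 0.0701), quorum sensing (adjusted p = 0.125) and iron (adjusted p = 0.214), besides ribosomal proteins, and iron was gained at 10 min (adjusted p = 0.0392). With the lowest 40% left out iron and quorum sensing were lost from 10 to 60 min (adjusted p = 0.123 and 0.0613) and iron was gained at 10 min (adjusted p = 0.0491). With fry, besides the lists named above, DNA repair (adjusted p = 0.0153) and pili (adjusted p = 0.00551) passed at 10 min. At 60 min fry passed the PhoPQ and PmrAB list (adjusted p = 0.0149), envelope stress (adjusted p = 0.00533), oxidative stress (adjusted p = 0.0352), phosphate starvation (adjusted p = 0.0170) and quorum sensing (adjusted p = 0.0129), and from 10 to 60 min phosphate starvation (adjusted p = 0.00311).

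Between 10 and 60 min 247 of 4705 probe sets differed (74 higher, 173 lower at 60 min), 49 at least 2-fold (13 higher, 36 lower), with 841 at an unadjusted p under 0.05. By the ratio of average signals 14 were at least 2-fold higher and 34 lower. The groups did not overlap for 22.4% of probe sets, where chance gives 10%. Median centring gave 319 (37 higher, 282 lower), 201 of them shared with the 247, and the count was 153 without 10 min replicate 1.

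**Figure D3:**
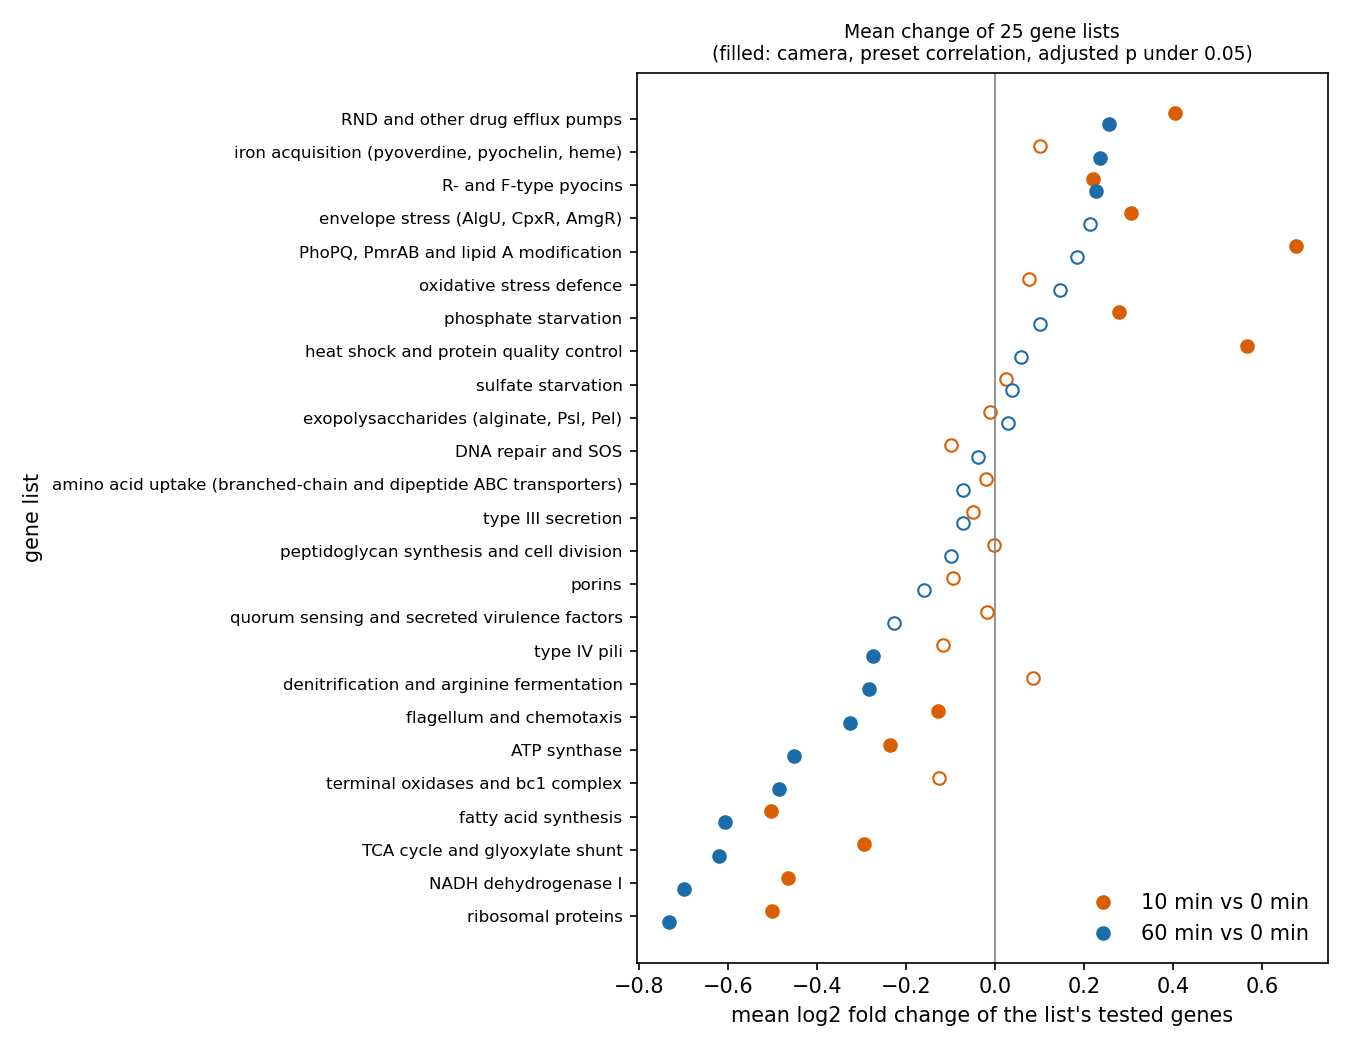
Mean log2 fold change of the tested genes of 25 gene lists at 10 min and at 60 min against untreated arrays, with filled points for lists past the camera test with a preset correlation. The PhoPQ and PmrAB list lies highest at 10 min (0.68) and ribosomal proteins lowest at 60 min (-0.73); after median centring the PhoPQ and PmrAB mean at 60 min turns from 0.18 to -0.03 and the heat shock mean from 0.06 to -0.49.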

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

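The explanation by time in culture was written only after the result was seen, and the compression test was moved to median-centred values after its first result was seen.

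The log2 changes of 62 named genes and the mean changes of 11 lists differed between 60 and 10 min by the direct test. Many of these genes were named because they passed this test, so their number is no separate result. Of all tested probe sets 247 of 4705 differed. Each value below is the change at 60 min minus that at 10 min. Genes with a higher value at 60 min, 11 in number, were rpsT (2.19), algU (1.16), ahpC (1.01), poxA (0.94), PA2826 (0.90), secE (0.88), rimM (0.86), tonB1 (0.81), aspA (0.77), chpA (0.48) and putA (0.38). Of these, ahpC (0.04), poxA (0.47), secE (0.09), tonB1 (0.25) and putA (0.11) lost the call after median centring, and chpA turned to -0.05. The other 51 had a lower value at 60 min. The largest differences were those of ccoO2 (-1.90), pilA (-1.77), rpmC (-1.72), mexC (-1.59), wbpG (-1.58), ccoN2 (-1.53), PA4773 (-1.52), nfxB (-1.50), PA1559 (-1.46), arcC (-1.40), trpB (-1.39), rplX (-1.39), dnaK (-1.38), arcA (-1.36), arcB (-1.31) and clpX (-1.30). They were followed by fliC (-1.18), rplO (-1.15), oprE (-1.12), sdhC (-1.06), atpH (-1.05), oprG (-1.05), pqsB (-1.05), hcnA (-1.04), clpB (-1.01), mexD (-1.01), bfrB (-1.01), oprD (-0.998), PA1343 (-0.98), PA5212 (-0.95) and PA4933 (-0.93). Smaller differences were found for PA4430 (-0.90), ftsZ (-0.89), arnB (-0.82), ftsA (-0.81), flgE (-0.80), nuoJ (-0.79), hcnC (-0.79), nuoI (-0.78), sdhA (-0.78), pilQ (-0.77), pstC (-0.76), mucD (-0.71), narG (-0.70), acnA (-0.69), PA2019 (-0.67), desA (-0.66), phoB (-0.63), PA2604 (-0.63), fliD (-0.60) and fabG (-0.51).

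The lists that were higher or lower at 60 min than at 10 min were PhoPQ, PmrAB and lipid A modification (-0.49), NADH dehydrogenase I (-0.23), terminal oxidases and bc1 complex (-0.36), denitrification and arginine fermentation (-0.37), TCA cycle and glyoxylate shunt (-0.33), ribosomal proteins (-0.23), heat shock and protein quality control (-0.51), iron acquisition (pyoverdine, pyochelin, heme) (0.13), flagellum and chemotaxis (-0.20), type IV pili (-0.16) and quorum sensing and secreted virulence factors (-0.21). Of these, the PhoPQ and PmrAB list and the flagellum list passed with an estimated correlation (adjusted p = 0.0250 and 0.0480 with an estimated correlation). The other 9 did not.

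The fall of ribosomal protein genes at 60 min against 0 min (median -0.72) was weighed. A general loss of mRNA signal would lower all genes. Under Bacillus subtilis control scaling, an alternative chosen after the data were seen, their median was 0.55 (0.40 to 0.67 with arrays left out). The ribosomal protein median was -1.45. Gene signal as a whole thus did not fall relative to these controls. A general loss of mRNA itself stays open, because the same amount of RNA was labelled for every array. Signal other than mRNA may also have lifted the gene median. The intergenic median was 0.709 ± 0.0367 (SD, n = 3) of the gene median on untreated arrays and 0.823 ± 0.0467 (n = 3) at 60 min. Compression of bright signals stays open: after median centring, level-matched genes outside the lists had a median of -0.81 (middle 95% of draws -0.98 to -0.47) and ribosomal protein genes -2.02. On quantile-normalized values the matched median was 0.20 (0.05 to 0.38), but that normalization fixes the average of bright probe sets and so decides nothing. Time in culture cannot be told apart from the exposure, as no untreated culture at 60 min was analysed here. The ribosomal protein median at 10 min was already -0.42, and a response to chlorhexidine itself stays open, untested apart from time.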

How the results depend on the processing

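Scaling to Bacillus subtilis control probe sets, the limit to genes above intergenic probe sets, the fit without the dimmest arrays and the ratio on deposited signals were tests chosen after the data were seen. So were, for the gene lists, median centring, the 40% filter, the pseudocount, the floor and the fit without a variance trend. The cause was not tested for any change below, except where fewer arrays or genes were fitted.

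Of 244 calls of named genes, 169 were kept in every leave-one-out fit and 75 were lost in at least 1. Many named genes were chosen for large changes or for passing the test in these same arrays. These counts therefore do not describe calls in general. Among all tested probe sets, single leave-one-out fits kept 192 to 346 of the 351 calls at 10 min. At 60 min they kept 490 to 782 of the 867. Deposited signals moved the median log2 change of all probe sets to 0.75, 0.92 and 0.17 in the 3 comparisons, and control scaling to 0.35, 0.56 and 0.21; single-gene values under both are relative to these.

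The 351 probe sets changed at 10 min became 59 (57 higher) with deposited signals, 660 (176 higher) with median centring, 92 (66 higher) with control scaling, 171 of the 873 tested above intergenic level, 178 without the dimmest arrays, 57 at 2-fold and 8 with a variance not pooled across genes, and 201 to 416 with arrays left out. The 867 at 60 min became 2073 (2023 higher) with deposited signals, 1170 (1057 higher, 113 lower, 395 of the 867 kept) with control scaling, 416 of the 873 tested above intergenic level, 354 without the dimmest arrays, 99 at 2-fold, and 510 to 840 with arrays left out. With a variance not pooled across genes the count was 0, with 967 at an unadjusted p under 0.05, against 867 and 1577 with limma. The 247 from 10 to 60 min became 8 with deposited signals, 42 with control scaling, 71 without the dimmest arrays, 162 with only the 6 arrays compared, 49 at 2-fold and 1 with a variance not pooled, and 153 to 288 with arrays left out. With the replicate block the counts were 392, 938 and 269. Deviations from the group means correlated at r = -0.0236 to 0.260 across probe sets in the 9 pairs of arrays of different groups with the same number, over 0.1 in 3 of them. In such pairs with other numbers r was -0.255 to 0.0583. The main fit has no block because the labels do not say that a replicate number marks a shared culture or day. Between 10 and 60 min r was 0.260 for replicates 2 and 0.246 for replicates 3, against -0.254 and -0.255 for these arrays crossed. For replicates 1 it was -0.00499. The remaining pair over 0.1 was that of the untreated and 10 min replicates 1 (r = 0.125). Replicate 1 was the dimmest array of every group, so the fit without the dimmest arrays is also a fit without replicates 1. A shared culture or day thus stays open, between 10 and 60 min arrays and for the untreated arrays.

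The numbers at least 2-fold by the ratio of average signals, 56, 99 and 48, became 111, 178 and 78 without a filter and, in both comparisons with untreated arrays, 816 and 1691 with deposited signals. The 35 list shifts became 5 with an estimated correlation and 19 above intergenic level, where 69 of the 75 tests could be run, and were 31 to 35 with arrays left out. Median centring gave 40 list shifts, 34 of the 35 among them, and deposited signals and control scaling each gave 39, with 33 of the 35. List sizes relative to all tested genes are the same under these scalings by construction, so their like counts are no separate support. Fry lost 4 of the 35 and added 10, and the limit above intergenic level lost 19 and added 3. The overlap of 216 became 47 with deposited signals, and 115 to 241 with arrays left out.

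Signs turned for bright genes. At 60 min against 0 min median centring gave rpsT -1.54, groEL -1.33, ahpC -0.35, himA -0.0877, rpoH -0.15, PA0622 -0.15, grpE -1.05, tonB1 -0.000164, chpA -0.0889, secE -1.35 and putA -0.41. Relative to the median shift, deposited signals and control scaling both gave rpsT -1.53, groEL -1.32, ahpC -0.335, himA -0.0732, rpoH -0.13, PA0622 -0.135, grpE -1.04, chpA -0.0743 and secE -1.34. Median centring, deposited signals and control scaling differ only by a constant for each array. Their values are thus alike by construction and give no separate support. From 10 to 60 min median centring gave oprJ -0.86, groEL -0.99, himA -0.54, PA3691 -0.575, grpE -0.84 and chpA -0.0530, and the other scalings gave chpA -0.0482. The flagellum list at 10 min turned to 0.15 relative to all tested genes above intergenic level, where 2 members were tested (adjusted p = 0.910). Intergenic signal close to gene signal limits what can be read from dim genes.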

Other observations

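All tests below were chosen before their results were seen, but the short-RNA test was reread after its value was seen, and the spread and other scalings of the intergenic probe sets were looked at after their median.

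Neighbouring genes changed together. At 10 min the 4 genes oprJ, mexD, mexC and nfxB rose in a row (mean log2 change 2.32), as did PA4773 to pmrB (5 genes, 0.81) and arnB, arnC and arnA (0.91), while rplS, trmD, rimM and rpsP fell (-1.40). At 60 min the 9 TCA cycle genes from gltA to sucC fell (-0.95), as did 8 NADH dehydrogenase genes from nuoB to nuoJ (-0.84) and hcnA, hcnB and hcnC (-1.44). From 10 to 60 min arcA, arcB and arcC fell (-1.36), as did ccoP2, ccoO2 and ccoN2 (-1.53). These runs were chosen after their values were seen. There were 10, 32 and 10 runs of 3 or more genes in the 3 comparisons, against at most 3, 12 and 3 in 200 random orders. Log2 changes of adjacent genes correlated at r = 0.318, 0.328 and 0.263 over 3754 pairs, above the highest of 1000 random orders (0.0594, 0.0486 and 0.0427). Genes are not independent replicates. The lowest of these values is what genes of one transcription unit that change together would give, and it may also hold a share from neighbours of like function.

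Probe sets for tRNA moved between the exposure times. Of 14 tested, 3 were lower at 10 min (median log2 change -0.25), 5 higher and 1 lower at 60 min (0.33), and 7 higher from 10 to 60 min (0.74; 0.39 after median centring). A changing share of genomic DNA would move the intergenic probe sets as well. Of 126, 9 were higher and none lower, a larger share than the 57 of 4562 gene probe sets that were higher. Their median was 0.0540 (SD 0.25), and the tRNA median lay above theirs by 0.68, or by 0.35 (SD 0.20) after median centring and with control scaling. Median centring and control scaling give the same difference by construction. With control scaling the intergenic median was 0.25 and the tRNA median 0.60. The limit set in advance for rejecting DNA was a share of the tRNA median. With quantile normalization that limit was 0.18, and the intergenic median lay below it. That normalization and median centring hold the bulk of probe sets in place, which largely fixes a small intergenic median in advance. Control scaling does not, and there the intergenic median lay above the limit of 0.15. The tRNA probe sets thus moved further than the intergenic ones, but a cause in DNA stays open. A better recovery of short RNA would raise short genes, and 219 genes of 300 bp or less lay 0.0368 above level-matched longer genes (middle 95% of draws 0.00284 to 0.0676). Short genes can lie on long transcripts, so that test leaves the recovery of short RNA open, a reading made after its value was seen. A response of tRNA to the exposure or to time in culture stays open and was not tested.

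Intergenic probe sets lay near the gene probe sets and far above those for genes of other strains. Of 99 regions probed on both strands, 85.9% had both strands above 4 times the other-strain median on all 3 untreated arrays, 94.9% at 10 min and 96.0% at 60 min. Of the gene probe sets 97.6% to 99.7% per array did, and of those for other strains 12.8% to 24.8%. Signal from both strands is what genomic DNA in the labelled material would give, so DNA may be one source. The intergenic medians lay at 13.6 to 20.2 times the other-strain medians, so the limit of 4 times restates much of the pattern. Passing it adds little support. The means of the strands correlated across regions at r = 0.178. RNA read from one strand would make the strands differ at least as much as random pairings do. The strands of a region differed by a median of 0.462 (log2), near the lowest of 1000 random pairings (median 0.719, range 0.457 to 0.929). The value was lower than that explanation predicts. The limit set in advance, a value under all pairings by more than their spread, was not reached, so the explanation stays open.

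The 6 arrays of each comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 351 changed probe sets at 10 min and the highest other split 1, the real split gave 867 at 60 min and the highest other 0, and from 10 to 60 min these were 247 and 0.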
